A study of Mus musculus with 12 samples.

How the data were processed

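The series holds 12 ATAC-seq libraries of passage 2 mouse embryonic fibroblasts, 3 in each combination of genotype (wild type or PIN1 knockout) and serum state (starved for 48 h in 0.2% FBS, or restimulated for 4 h with 20% FBS). Groups were taken from the labels. Libraries were made with the Omni-ATAC protocol, per the labels' protocols. The submitters' processing notes name the mm10 build, CASAVA 1.8.2 and SAMtools without saying what each was used for. The aligner, the peak caller and its threshold, the correction of read positions for transposase insertion, the removal of duplicates or of blacklisted regions, and the rule by which peaks were joined are not given in the sources used here.

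The authors deposited 1 list of genomic intervals for the whole series, a union of peaks by its name. It gives chromosome, start, end and a name that repeats them, and holds no count, score, coverage or sample label. Intervals were sorted and 0 pairs overlapped or touched, and the smallest gap between neighbours was 1 bp. A minimum width of 500 bp, shared by 31.4% of intervals, shows that the set has a fixed lower width, so widths near it carry little information on the size of an open site. A union over libraries grows with depth and with the number of libraries, and a site open in 1 library counts as much as one open in all 12. Starts were read as counted from 0 and are printed counted from 1.

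Tests of differences between groups needed values per sample and were not made. Neither were those that need a sequence or transcript annotation: motif enrichment, the split of gene bodies into exons and introns, and matching on promoter CpG content. Genes came from a RefSeq table of GRCm38.p6, the assembly that mm10 names, with 49554 genes of any type and 21631 protein-coding genes on these 20 chromosomes. The table gives start and end without strand. Measures meant for transcription start sites were therefore made at both ends of each gene, and the matching of random lists on promoter CpG content was replaced by matching on local gene density. A gene-end peak overlaps, by 1 bp or more, the window of 1 kb around either end. The number of nearby peaks counts those within 50 kb of an end but not within 1 kb of it, averaged over the gene's 2 ends.

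Shares of peaks by annotation were compared with 100 placements of the same peaks at random between the first and last feature of their chromosome. Shares of genes were compared with 100 circular shifts of the peaks, which keep their spacing. Assembly gaps were not masked, so random placement can fall in them. The 17 gene lists, with 287 different genes of which all were matched by symbol, were fixed before the data were examined. Each list's share or median was compared with 10000 random lists of protein-coding genes with the same number from each of 10 classes of local gene density (protein-coding gene ends within 50 kb). P values are two-sided permutation p values, adjusted by the Benjamini-Hochberg method over the 17 lists for each measure, with a threshold of 0.05. They describe 1 peak set over genes and say nothing about differences between animals or cultures. The correlation across chromosomes used 100000 permutations.

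Genes were named by a rule fixed before the data were examined. It takes Myc and Pin1, for each list the 2 members with the most and the 1 with the fewest nearby peaks and any members without a gene-end peak where these were 5 or fewer, the 10 protein-coding genes with the most nearby peaks, and the gene nearest to each of the 5 widest peaks. Where a list had more than 5 members without a gene-end peak, and for examples of members with one, genes were named after their values were seen. Alternatives covered the gene-end window, the peak midpoint, the gene types, the random lists, the window for nearby peaks, covered base pairs and peak width. Matching on gene length, circular shifts for the annotation shares and for peak widths at gene ends, and the restriction to peaks wider than 500 bp were added after seeing the data.

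The list test was tested on simulated data on 21631 genes with lists of 18. Of 200 lists drawn at random, 3.5% had an unadjusted p under 0.05. For the share of genes with a gene-end peak, 95.5% of lists with a true share of 97% and 78.5% of lists with a true share of 30% did so. For the number of peaks near genes, 94.5% of lists with 1.5 times the peaks did so. The simulated background share rose with gene density and was on average lower than the real share of 73.8%. Simulated numbers of nearby peaks were drawn independently for each gene, unlike real ones. These rates are therefore not the power of the tests on the real lists, and a lower background makes high shares easier to detect. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.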

Results

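Accessible chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in primary mouse embryonic fibroblasts (MEFs) at passage 2. The fibroblasts were wild type or lacked PIN1, a prolyl isomerase that acts on phosphorylated proteins and has MYC among its substrates. Cells were deprived of serum for 48 h in medium with 0.2% FBS and were collected either in that state or 4 h after addition of medium with 20% FBS, a treatment that induces the transcription factor MYC. The 12 libraries fall into 4 groups of 3: starved wild type, stimulated wild type, starved knockout and stimulated knockout. The design implies comparisons of serum stimulation within each genotype, of genotype within each serum state, and of the serum response between genotypes. The values analysed here are the positions of one set of peaks pooled over the series, in which no peak is assigned to a sample or group. None of these comparisons was therefore tested, and every value below describes sites that were open in at least some of the fibroblast samples. Read depth per sample is unknown, and no value has a replicate error.

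The pooled set held 203950 peaks on the 19 autosomes and the X chromosome (mm10). Together the peaks covered 133 Mb, or 5.10% of the 2613 Mb analysed. The median width was 559 bp, with an interquartile range of 500 to 679 bp and a maximum of 4579 bp. No peak was narrower than 500 bp, and 64010 peaks (31.4%) had exactly that width. Peaks over an end of a protein-coding gene were wider than the rest. The 12464 such peaks had a median width of 1065 bp and 5.78% of them were 500 bp wide, whereas the 137889 peaks over 5 kb from any gene end had a median of 549 bp and 33.6% were 500 bp wide. A wider peak is likelier to cover any given base, and over 100 circular shifts of the peaks along their chromosomes those that fell on such ends had a median width of 601 bp (range 588 to 611 bp).

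Both genes named in the study's design lay in open chromatin. Myc (Gene ID 17869; chromosome 15, 61985341 to 61990361) had a 1150 bp peak over its lower-coordinate end, at 61984748 to 61985897. A 921 bp peak at 61986550 to 61987470 and a 507 bp peak at 61987555 to 61988061 lay within the gene. There were 12 peaks in the Myc gene and the 50 kb on either side. Of the 9 that did not touch the gene, 2 lay below it and 7 above. The most distant cluster, 3 peaks between 62037619 and 62039559, lay about the lower end of Pvt1, a long non-coding RNA gene that starts at 62037986. Pin1 (Gene ID 23988; chromosome 9, 20652118 to 20663712) had a 1034 bp peak over its lower-coordinate end, at 20651495 to 20652528. One further peak of 629 bp lay inside the gene and another of 927 bp lay 181 bp above its upper end. In all, 9 peaks fell in Pin1 and the 50 kb on either side, including peaks in the neighbouring genes Fbxl12, Ubl5 and Olfm2. Because knockout and wild-type libraries were pooled, the peak over Pin1 gives no information on the knockout allele.

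Peaks were concentrated at the ends of genes. Of all peaks, 30814 (15.1%) lay within 1 kb of an end of an annotated gene of any type, 96713 (47.4%) lay elsewhere in a gene body and 76423 (37.5%) were intergenic. When the peaks were placed at random on their chromosomes 100 times, gene ends received 8.03% of them (range 7.83 to 8.16%), gene bodies 43.4% (43.2 to 43.7%) and intergenic sequence 48.5% (48.2 to 48.9%). Gene ends thus held 1.88 times the share expected from random placement, gene bodies 1.09 times and intergenic sequence 0.772 times. Each two-sided permutation p was 0.0198, the smallest that 100 placements can give. The strand of each gene was not used here, so the end that holds the transcription start could not be told from the other, and both were counted.

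Most protein-coding genes had an open end. A peak lay within 1 kb of at least one end of 15961 of 21631 protein-coding genes (73.8%), against 32.7% on average over 100 circular shifts of the peaks along their chromosomes (range 31.1 to 34.1%). A peak covered the end base itself in 12984 genes (60.0%), against 10.0% after shifting. Both ends were covered in 862 genes (3.99%), against 0.383% after shifting. Averaged over both ends, 32.0% of gene ends were covered, and this fell to 13.5% at 1 kb on the gene side and to 8.54% at 1 kb outside. At 10 kb the covered shares were 6.83% on the gene side and 6.66% outside. In genes shorter than the distance, the point on the gene side lies beyond the other end.

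**Figure D1:**
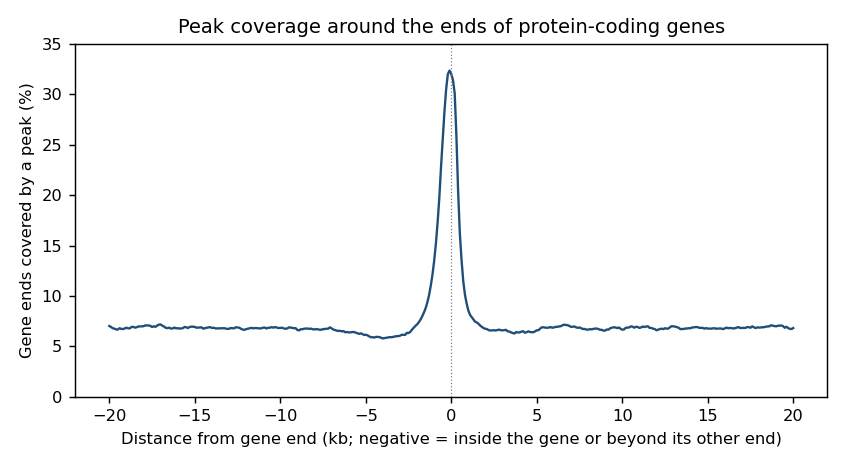
Share of protein-coding gene ends (%) covered by a peak, against distance from the end in kb, with both ends of 21631 genes averaged. Negative distances point into the gene and, in genes shorter than the distance, lie beyond its other end. Coverage is 32.0% at the end itself and lies near 7% from about 5 kb outward.

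Immediate early genes, MYC-target genes of ribosome biogenesis and of metabolism, and E2F and DNA replication genes had open ends more often than matched genes. Among 27 immediate early genes, which are transcribed within minutes of growth factor addition, 26 (96.3%) had a peak within 1 kb of an end, against 71.1% in random lists of protein-coding genes matched on local gene density (central 95% of lists 51.9 to 88.9%; adjusted permutation p = 0.0147). Fos, Fosl1, Jun, Junb, Egr1, Ier2 and the matricellular genes Ccn1 and Ccn2 all had a peak over an end. Egr2 was the exception, with its nearest peaks 1435 and 3017 bp from its ends and 3 peaks overlapping the gene. All 19 ribosome biogenesis genes known as MYC targets, among them the nucleolar protein genes Ncl, Npm1 and Fbl, had a peak over an end base. Their share within 1 kb (100%) compared with 71.8% in matched lists (adjusted permutation p = 0.0153). All 18 MYC-target metabolism and growth genes had a peak within 1 kb of an end, including Odc1, which encodes the first enzyme of polyamine synthesis, and Cad, which encodes the first steps of pyrimidine synthesis (70.5% in matched lists; adjusted permutation p = 0.0153). All 19 E2F and DNA replication genes, among them Ccne1, Pcna and Mcm2 to Mcm7, also had one (72.8% in matched lists; adjusted permutation p = 0.0153). For the metabolism and growth genes the difference no longer passed when random lists were matched on gene length (adjusted permutation p = 0.0602). Families of broadly used genes, chosen after the peaks were seen, had similar shares within 1 kb. These were 96.25% for ribosomal protein genes and 95% each for proteasome subunit and mitochondrial complex I genes. High shares were therefore not particular to these lists.

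Of 26 nuclear pore genes, 24 (92.3%) had a peak within 1 kb of an end, against 72.1% in matched lists (adjusted permutation p = 0.0399). Nup153 and Tpr, which encode components of the nuclear basket, and Nup98 and Nup107 had a peak over an end. Nup160 and Pom121 did not have one within 1 kb, the nearest peaks being 1552 bp and 4104 bp from an end. The nuclear pore difference of 20.2 percentage points no longer passed against lists matched on gene length (9.90 points, adjusted permutation p = 0.380), against lists of any protein-coding genes (18.6 points, adjusted permutation p = 0.0722) or with only peaks wider than 500 bp (20.9 points, adjusted permutation p = 0.0607). It passed when a peak had to cover the end base (23 of 26; 29.9 points, adjusted permutation p = 0.00623). Of 21 genes of the MYC network and MYC turnover, 19 (90.5%) had a gene-end peak, which did not pass the test (73.4% in matched lists; adjusted permutation p = 0.169). Myc, Mycn, Mycl, their partner Max, the antagonists Mxd1, Mxd3, Mxd4 and Mnt, and the turnover genes Fbxw7, Gsk3b and Pin1 had a peak over an end, whereas Skp2 and Axin1 had none within 1 kb. The histone acetyltransferase complex genes, among them Kat2a and Ep300 (10 of 10; 74.0% in matched lists; adjusted permutation p = 0.149), and the actin cytoskeleton genes controlled by SRF (15 of 16; 72.8% in matched lists; adjusted permutation p = 0.147) did not pass either. For the histone acetyltransferase list, 10 of 10 is the highest share possible, and its unadjusted permutation p was 0.0878. A list of this size could not pass by a higher share, so the test does not decide whether these genes differ. Fhl2 was the actin-list member without a gene-end peak, its nearest peak lying 1710 bp from an end.

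Every fibroblast gene of its list had a peak within 1 kb of an end, whereas most hepatocyte, pluripotency and germ cell markers did not. All 29 fibroblast and extracellular matrix genes had a peak within 1 kb of an end, against 75.5% in matched lists (adjusted permutation p = 0.0102). They included the collagen genes Col1a1, Col1a2 and Col3a1, fibronectin (Fn1), the PDGF receptor genes Pdgfra and Pdgfrb, and the mesenchymal transcription factor genes Twist1 and Prrx1. A peak covered an end base in 26 of the 29, all but Postn, Prrx1 and Fap (61.7% in matched lists, adjusted permutation p = 0.0068). Of 12 pluripotency and germ cell markers only 3 (25%) had such a peak, namely Utf1, Dazl and Prdm14, against 73.9% in matched lists (adjusted permutation p = 0.0119). Pou5f1, Nanog and Zfp42 were among those with none. Dppa3, Esrrb, Lin28a and Nanog missed the window narrowly, with peaks 1051, 1244, 1284 and 1296 bp from an end. In the other members without such a peak, the nearest lay from 2044 bp (Pou5f1) to 24579 bp (Zfp42) away. A wider gene-end window was not run for the lists. Of 12 hepatocyte markers 4 (33.3%) had a gene-end peak, against 72.5% in matched lists (adjusted permutation p = 0.0267). Alb, Ttr and Hnf4a were among the 8 without. When only peaks wider than 500 bp were counted, the hepatocyte count was still 4 of 12 and the difference from matched lists was -34.6 in place of -39.2 percentage points, which no longer passed (adjusted permutation p = 0.0616).

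Blood cell markers had a peak within 1 kb of an end in 10 of 17 genes (58.8%; 71.0% in matched lists; adjusted permutation p = 0.510). A peak covered the end base of only 2 of these 17 genes, Csf1r and Coro1a, and on that measure the list lay below its matched lists (11.8% against 57.3%; adjusted permutation p = 0.0034). The difference from matched lists did not pass the test for endothelial markers (6 of 11; 75% in matched lists; adjusted permutation p = 0.329), muscle markers (8 of 12; 74.0%; adjusted permutation p = 0.812), neural markers (9 of 12; 77.3%; adjusted permutation p = 1), epithelial markers (12 of 14; 74.0%; adjusted permutation p = 0.612) or adipocyte, cartilage and bone markers (10 of 12; 74.2%; adjusted permutation p = 0.812). For the endothelial, muscle, neural and adipocyte, cartilage and bone lists, the central range of the matched lists reached 100%. These small lists could therefore not have passed by a higher share, and the test bears only on lower shares. Members without a gene-end peak were Pecam1, Emcn, Vwf, Robo4 and Egfl7 for endothelium, Myog, Myf5, Myh6 and Myh7 for muscle, Neurod1, Gfap and Sox10 for neural cells, Krt5 and Krt18 for epithelium, and Adipoq and Bglap for the adipocyte, cartilage and bone list. Bglap, Myh7, Pecam1, Vwf, Egfl7, Myog and Neurod1 missed the window narrowly, with peaks 1121 to 1286 bp from an end. In the rest, the nearest peak lay from 1497 bp (Krt18) to 5911 bp (Sox10) away. Among the members with a gene-end peak were Myod1, a muscle-determining factor, and Sox9, Runx2 and Pparg, which direct cartilage, bone and fat differentiation. Random lists could not be matched on promoter CpG content, which is known to go with promoter accessibility.

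**Figure D2:**
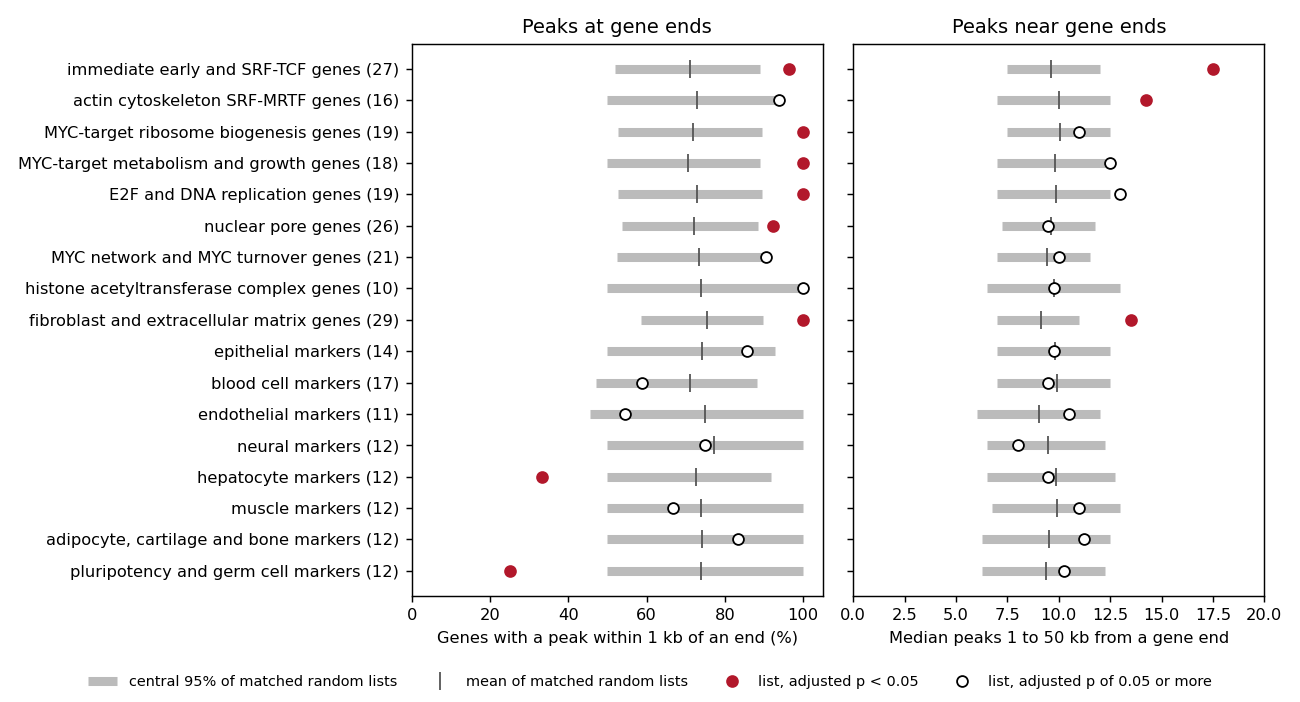
Left, share of genes (%) with a peak within 1 kb of an end; right, median number of peaks 1 to 50 kb from a gene end, for 17 gene lists (number of genes in brackets). Grey bars are the central 95% of 10000 random lists matched on local gene density, ticks their mean, and filled points lists with adjusted p under 0.05, of which 8 are on the left and 3 on the right.

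More peaks lay around immediate early, actin cytoskeleton and fibroblast genes than around matched genes. The median number of peaks between 1 and 50 kb from a gene end, averaged over both ends of a gene, was 10 for all protein-coding genes. It was 17.5 (interquartile range 13.5 to 18.5) for the immediate early genes, against 9.63 in matched lists (central 95% 7.5 to 12; adjusted permutation p = 0.0017). Fosl1 had 21 such peaks, Junb 20.5 and Klf4, the lowest of the list, 9. The fibroblast and extracellular matrix genes had a median of 13.5 (11 to 16.5), against 9.13 in matched lists (adjusted permutation p = 0.0017), with 25 near S100a4, 22.5 near the fibrillin gene Fbn1 and 7.5 near Col6a1. Both unadjusted p values were the smallest that 10000 random lists can give (0.0002). Some fibroblast list members are neighbours, such as Col3a1 and Col5a2 or Dcn and Lum, so their windows share peaks. Random lists were drawn without regard to such neighbours, and the p value counts shared peaks as separate. The actin cytoskeleton genes had a median of 14.2 (13 to 16.1), against 9.99 (adjusted permutation p = 0.0159), with 20.5 near Tagln2, 19 near Tpm1 and 9 near Lima1.

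The other 14 lists did not pass the test for this number. The E2F and DNA replication genes had a median of 13 against 9.88 (adjusted permutation p = 0.0986), with 20 near Mcm2, 19 near Cdc6 and 5.5 near Mcm4. The MYC-target metabolism and growth genes had 12.5 against 9.83 (adjusted permutation p = 0.171), with 18.5 each near Hk2 and Shmt2 and 7.5 near Shmt1. The ribosome biogenesis genes had 11 against 10.1 (adjusted permutation p = 0.943), with 16 near Mybbp1a, 14 near Nop2 and 3.5 near Wdr12. The nuclear pore genes had 9.5 against 9.63 (adjusted permutation p = 1), from 15 near Aaas and Nup210 to 5 near Nup160. The MYC network and turnover genes had 10 against 9.41 (adjusted permutation p = 1), with 17 near Mycl, 15.5 near Mnt, 9.5 near Myc, 6.5 near Pin1 and 4 near Mxd4. The histone acetyltransferase genes had 9.75 against 9.79 (adjusted permutation p = 1), with 15.5 near Kat2a, 13 near Tada2b and 4 near Crebbp.

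In the marker lists of other cell types the medians ran from 8 for neural markers to 11.2 for adipocyte, cartilage and bone markers, and the smallest adjusted permutation p was 0.83. The most and fewest peaks were found near Krt8 (18), Cldn3 (17.5) and Krt5 (3.5) among epithelial markers, and near Hba-a1 (14), Laptm5 (13) and Hbb-bt (4) among blood cell markers. Endothelial markers ran from 16.5 near Egfl7 and 15 near Robo4 to 7 near Emcn, and neural markers from 10 near Dlx2 and Gad1 to 5.5 near Stmn2. Hepatocyte markers ran from 16.5 near Apoa2 and 12.5 near Apoa1 to 5.5 near Alb, and muscle markers from 18.5 near Des and 17 near Tnnt2 to 7 near Myod1. Near Sp7 and Fabp4 there were 17 and 13.5 peaks and near Acan 7.5, and near Dppa3 and Utf1 there were 18 and 17 and near Zfp42 4.5. When covered base pairs were counted in place of peaks, the E2F and DNA replication genes (adjusted permutation p = 0.0085) and the MYC-target metabolism and growth genes (adjusted permutation p = 0.0415) also lay above their matched lists. With only peaks wider than 500 bp the E2F and DNA replication genes passed (adjusted permutation p = 0.0493), and with a 10 kb window the metabolism and growth genes did (adjusted permutation p = 0.0467).

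Across the genome, 6 of the 10 protein-coding genes with the most peaks 1 to 50 kb from their ends were histone genes of one cluster on chromosome 13, led by H3c8 with 29.5 peaks. The histone genes H3c7, H2ac10, H2bc9, H4c6 and H1f3 had 26 to 27.5. The others were Phlda3 (28) and Csrp1 (26), neighbours on chromosome 1, Sfi1 (27) and Gm45521 (26.5). The 6 histone genes lie so close together that their windows count largely the same peaks, and the windows of Phlda3 and Csrp1 overlap too. The ranking thus repeats single loci. Histone gene copies are alike in sequence, so the counts at single members of that cluster are uncertain.

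Peak density was even between autosomes and lower on the X chromosome. The 19 autosomes had a mean of 81.5 peaks per Mb (SD 4.85, n = 19 chromosomes), from 73.4 on chromosome 14 to 90.8 on chromosome 19. The X chromosome had 35.2 peaks per Mb, 0.431 times the autosomal mean. Across the autosomes, peak density was not significantly related to the density of protein-coding genes (Pearson's r = 0.364, permutation p = 0.128; Spearman's rho = 0.398, permutation p = 0.0945; 1 relation examined). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.639 (permutation p = 0.00566) and rho 0.547 (permutation p = 0.0244), so the test depended on those chromosomes.

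**Figure D3:**
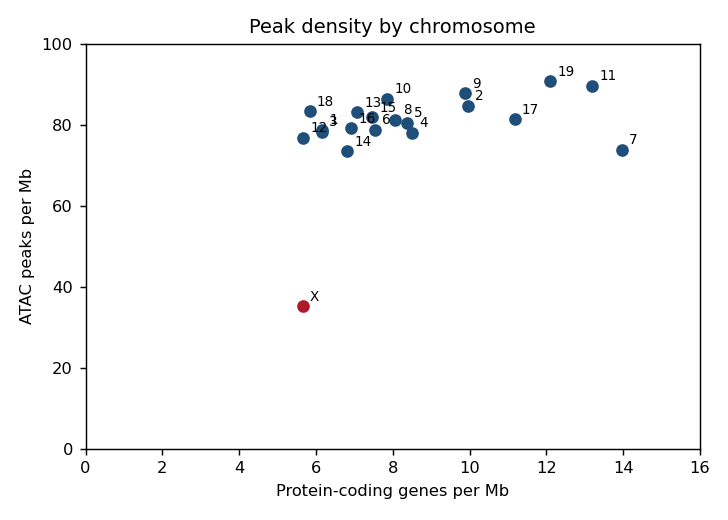
Peaks per Mb against protein-coding genes per Mb for each chromosome, 1 point per chromosome, with the X chromosome in red. The autosomes lie between 73.4 and 90.8 peaks per Mb and the X chromosome lies at 35.2.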

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

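No paired analysis was possible because the peak list gives no values per sample; for the same reason the alternatives on normalization, count filters, pseudocount, thresholds, overlap between samples, the block by replicate number and leaving out replicates were not run. The alternatives that need sequence or strand (all those for motifs, and 1 transcription start per gene) were not run either. Merging touching peaks, keeping the autosomes and X, and width minimums of 150 and 500 bp removed no peak and so test nothing. The ratios of peaks at gene ends, in gene bodies and in intergenic sequence to random placement kept their direction under the 4 other alternatives run, the first ranging from 1.52 with a 2.5 kb window to 2.51 with protein-coding genes only. Circular shifts, matching on gene length and the restriction to peaks wider than 500 bp were chosen after seeing the data. Differences below are a list minus its matched random lists.

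For gene-end peaks, in percentage points, blood cell markers lay below their matched lists when a peak had to cover the end base (-45.6, past the threshold). Nuclear pore genes no longer passed against random lists of any protein-coding genes (18.6), against lists matched on gene length (9.90) or with peaks wider than 500 bp only (20.9). MYC-target metabolism and growth genes no longer passed with length matching (21.1), nor hepatocyte markers with wider peaks (-34.6), where 1 list in place of 2 lay below its matched lists. Sign changes occurred only in lists that passed under neither setting: epithelial markers with the end base (-10.4) and with wider peaks (-5.35), and neural markers against any protein-coding genes (1.01).

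For nearby peaks, MYC-target metabolism and growth genes passed with the 10 kb window (1.12 peaks) and with covered base pairs (2.33 kb), and E2F and DNA replication genes with covered base pairs (2.70 kb) and with wider peaks (3.01 peaks), so that 5 lists in place of 3 lay above with covered base pairs. Sign changes again occurred only in lists that passed under neither setting. In peaks, with the 10 kb window these were ribosome biogenesis (-0.169), nuclear pore (0.405), histone acetyltransferase (0.0925), epithelial (0.350), neural (0.885) and pluripotency genes (-0.331). With the 100 kb window they were ribosome biogenesis (-0.576), epithelial (3.16), blood (1.66) and muscle genes (-0.316). With covered base pairs, in kb, they were histone acetyltransferase (0.541) and pluripotency genes (-0.340). With length matching it was the MYC network (-0.140), and with wider peaks the MYC network (-0.0615), epithelial (0.516) and pluripotency genes (-0.0125). The causes of these changes were not tested. Depth is unknown, so how many weaker sites the set misses cannot be stated.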

Other observations

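Gene families, dense windows and peak-free blocks were chosen for study after the peak positions had been seen; a test of whether 500 bp peaks were rarer at gene ends was dropped after its result was seen, because it only restated the pattern, and the X quotients without peak-free blocks were added after the first quotient was seen. Gene families differed in how often an end base was covered by a peak. Families of broadly used genes were mostly open: 71 of 80 ribosomal protein genes (88.8%), 37 of 40 proteasome subunit genes and 37 of 40 mitochondrial complex I genes (92.5% each). So were 317 of 397 Zfp zinc finger genes (79.8%). Circular shifts of the peaks gave 9.45 to 10.4% for these 4 families. Sensory receptor families lay below the shifted peaks. An end was covered in 29 of 1110 olfactory receptor genes (2.61%; 86 to 138 genes over 100 shifts) and in 5 of 353 vomeronasal receptor genes (1.42%; 21 to 48 genes). Of the vomeronasal receptor genes, 64.3% lay wholly inside peak-free blocks longer than 100 kb, as did 37.9% of olfactory receptor genes and 40.3% of defensin genes, against 5.72% of all protein-coding genes. Many of these receptor genes have close paralogs, between which reads can be hard to assign, and this was not tested. The longest autosomal peak-free block, 2.18 Mb on chromosome 7 (31292000 to 33475248), held 67 genes of any type, of which the 25 protein-coding genes all had Scgb (secretoglobin) symbols.

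The Hox genes, which record position along the body axis, had peaks at gene ends in all 4 clusters. A peak covered an end base in 27 of 39 of them (69.2%), against 60.0% of all protein-coding genes. On the wider 1 kb measure used next, all protein-coding genes reached 73.8%. Hox genes lie close together, so a single peak can count for several of them. A peak lay within 1 kb of an end in 36 of 39 Hox genes (92.3%; 4 to 27 genes over 100 shifts), including the posterior genes Hoxa13, Hoxc13 and Hoxd13; Hoxb1, Hoxc4 and Hoxd10 were the exceptions. Other families were 35 of 44 collagen genes, 27 of 31 integrin genes, 304 of 375 solute carrier genes, 26 of 53 keratin genes, 16 of 72 defensin genes and 12 of 35 cornified envelope and small proline-rich genes; the last 3 of these lay within the range of the shifted peaks (6 to 33, 9 to 36 and 0 to 25 genes). Among non-coding genes, an end was covered in 3811 of 12697 long non-coding RNA genes (1181 to 1378 over 100 shifts) and 198 of 1228 microRNA genes (47 to 101), and in 628 of 9852 pseudogenes, which lay below the shifted peaks (804 to 948).

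The tests on tRNA genes and on the X chromosome that follow were written down before their values were seen, though the lower number of peaks on the X was already known. An end was covered in 307 of 408 tRNA genes (75.2%), against a mean of 23.9 and a highest value of 39 genes over 100 shifts, which argues against chance overlap. Of 300 tRNA genes over 5 kb from any end of a protein-coding gene, 207 (69.0%) were covered, against a highest value of 31, which argues against nearness to protein-coding promoters. Small nuclear RNA genes, also present in many copies, were covered in 79 of 1003 cases (39 to 89 over the shifts), and small nucleolar RNA genes in 121 of 1340 (54 to 111), above the shifted range, but in 82 of 1064 over 5 kb from protein-coding gene ends (39 to 91), within it. A candidate explanation is that tRNA genes transcribed in fibroblasts are themselves open, as a hypothesis; reads shared between identical tRNA gene copies stay open as a technical explanation, since read assignment is not given in the sources used here.

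The X chromosome had 35.2 peaks per Mb, against 81.5 on the autosomes (SD 4.85, n = 19). Its lower gene density is argued against as the whole cause: the residual of the X from the autosomal line of peak density on gene density was -44.3 peaks per Mb, outside the leave-one-out residuals of the autosomes (-16.6 to 8.08). Long peak-free blocks are argued against as the whole cause too, since without intervals over 100 kb the X still had 59.2 peaks per Mb, below the lowest autosome (80.8), although its ratio to the autosomal mean moved from 0.431 to 0.676. Lower signal per locus, so that weaker sites miss the peak threshold, stays open. It predicted a lower X to autosome ratio away from gene ends than at them. It also predicted a higher share of 500 bp peaks on the X than on every autosome. Both parts were met in direction. The ratio was 0.428 for peaks per Mb over 5 kb from protein-coding gene ends and 0.720 for the share of genes with a covered end. Their quotient was 0.594, where single autosomes gave 0.875 to 1.10. It sets a density against a share of genes, which are unlike measures. For plain numbers of peaks the X to autosome ratios lay closer together, 0.571 away from these ends and 0.659 over them. Peaks of 500 bp made up 33.1% of X peaks, against at most 32.5% on an autosome. With the blocks left out of the length, however, the quotient was 0.931 (autosomes 0.882 to 1.25). With the genes inside them left out too it was 0.796, below the lowest autosome (0.899 to 1.08). Blocks are defined by the lack of peaks, so leaving them out raises the density or the covered share by construction. These shifts in the quotient and in the density ratio therefore do not show what the blocks cause. The test of lower signal per locus does not decide. Widths do not decide either. Over protein-coding gene ends, which the prediction did not cover, the 500 bp share was 4.55% on the X (autosomal mean 5.84%, lowest 4.52%). A single X in male cells, 1 silenced X in female cells and fewer distal regulatory sites could each lower the X density; no group of the design separates these, so no biological explanation was tested.

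Some of the widest peaks overlapped pseudogenes, and a dense window held ribosomal RNA genes. The repeat content of the sequence was not examined. The widest peak (4579 bp; chromosome 1, 24611570 to 24616148) overlapped the pseudogenes Gm10222 and Gm10925 and had Col19a1 as its nearest protein-coding gene, 23648 bp away. The next (4286 bp; chromosome 17, 39843051 to 39847336) overlapped Rn18s-rs5, a pseudogene with a ribosomal RNA name, and its nearest protein-coding gene was Esp38. The others overlapped Iqschfp (3628 bp), LOC108167694 (3477 bp) and Zfp91 (2967 bp). Of 100 kb windows, the median with any peak held 8 peaks. The densest, with 38, lay on chromosome 11 (3100001 to 3200000) over Sfi1, and one with 28 on chromosome 8 (123500001 to 123600000) held 36 ribosomal RNA genes as well as Afg3l1, Dbndd1 and Gas8. The second densest, with 33 peaks on chromosome 6 (114500001 to 114600000), overlapped no gene of any type in the annotation.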
